A study of Danio rerio with 6 samples.

How the data were processed

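RNA was measured in 6 samples of whole zebrafish embryos (Danio rerio, TL strain): 1 of untreated embryos at 5 hours post-fertilization (hpf), 1 of untreated embryos at 21 hpf, 2 of embryos injected with a morpholino against Spt5 and 2 injected with a control morpholino, the last 4 at 21 hpf. Per the labels' protocols, about 2.5 pmol of morpholino, tagged with carboxyfluorescein, was injected at the start of cleavage, total RNA was extracted with Sepasol and cleaned on RNeasy columns, and biotin-labelled cRNA was made by a one-cycle protocol for Affymetrix zebrafish arrays. Groups were taken from the sample titles. Where a morpholino binds the supt5h transcript is not given in the sources used here, so the supt5h signal is reported but not used to check the knockdown.

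The deposited values are probe set intensities on a linear scale with 1 decimal. The submitters' processing notes name GCRMA without a version. Its settings, and whether a scaling step followed, are not given in the sources used here. The deposited intensity columns do not share a distribution, as quantile normalization would give: their medians run from 18.1 to 43.8. The values were therefore taken to log2 and quantile normalized, over the 4 morpholino arrays for the comparison of morpholinos, over the 5 arrays at 21 hpf for comparisons with untreated embryos, and over the 2 untreated arrays for the comparison of ages. The written plan had named the deposited log2 values as the main setting. Quantile normalization became the main setting after the values were seen not to be normalized, and the as-deposited values are an alternative.

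Of 15617 probe sets, 115 Affymetrix control probe sets were left out. A probe set was tested where its normalized log2 intensity was at least 5 (an intensity of 32) on at least 2 arrays of the fit. For the comparison of ages, for which no filter had been fixed, it was at least 5 on at least 1 of the 2 arrays. Of 120 as-deposited values of 20 unspiked control probe sets, 1 reached 32. Where every array of a group lay below log2 5 and the other group did not, a fold is given as a lower limit, with the dim values raised to log2 5, together with the adjusted p of the fit to the measured values. In the platform annotation 10802 probe sets have 1 gene symbol, 135 several and 4680 none. Symbols of 10718 were updated through Entrez identifiers to the RefSeq gene table of assembly GRCz12tu, and 84 kept the platform symbol. No coordinates are given, since the arrays name no genome build. From that table only gene names and the span of each gene were used.

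Differences were tested with lmFit and eBayes of limma 3.58.1 in R 4.3.3, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. The comparison of morpholinos used the 4 morpholino arrays with 2 residual degrees of freedom per probe set. Comparisons with untreated embryos used the 5 arrays at 21 hpf, the lone untreated array being assumed to vary like the morpholino groups. The labels do not say that replicates came from separate clutches, so p-values of single probe sets measure only the spread between these arrays, which may be technical. The median within-group SD was 0.11 on the log2 scale, and the number of arrays limits the precision. Because 2 arrays stand against 2, probe sets at least 2-fold apart in every pair of arrays were also counted, with the same count in the 2 other splits as background. Where a gene had several probe sets, the one with the highest mean log2 over all arrays stood for it in lists. Of 817 genes with over 1 tested probe set, 11 had probe sets called in both directions. The untreated ages were compared as log2 differences with no test.

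Gene lists were tested with camera of limma, with a preset inter-gene correlation of 0.01, and again with an estimated one, adjusted over 26 lists. These lists, the tests, the rule for named genes and the first set of alternatives were chosen before the data were examined. Pathway lists were Spt5 and the elongation machinery, heat shock and chaperones, immediate early genes, p53 pathway and apoptosis, interferon and innate response, unfolded protein response, cell cycle and DNA replication, ribosomal proteins and oxidative phosphorylation. Patterning and stage lists were Hox genes, somite segmentation and Notch, blastula and gastrula regulators, and maternal and germ cell genes. Cell type lists were skeletal muscle, heart, erythroid, myeloid, vascular endothelium, pigment cells and neural crest, neuronal differentiation, neural progenitors and brain patterning, eye and lens, notochord and hatching gland, epidermis and periderm, yolk syncytial layer with liver and gut, and pronephros. A further 8 lists were chosen after the values were seen and adjusted among themselves: DNA repair, tubulins, splicing factors, lysosome and autophagy, translation factors, aminoacyl-tRNA synthetases, cholesterol synthesis and the proteasome. For the age difference, the median of a list or of a set of probe sets was placed among 10000 random sets of the same size, drawn from 20 bins of mean intensity.

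Genes were named by a fixed rule: supt5h, then the 12 largest falls and the 12 largest rises by log2 difference among called probe sets with 1 gene symbol that is not a clone or placeholder name, up to 4 members of each list by p, the 10 largest differences each way between ages among named genes with log2 of at least 8 in the brighter array, and the 5 largest each way between control morpholino and untreated embryos. Risen members of the muscle and erythroid lists that fall outside this rule were named after their values were seen, as were dct, some p53 list genes, the 4 probe sets without a gene name and the members named from the 8 added lists.

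The alternatives were no filter, a mean log2 of at least 6, a prior with an intensity trend or a robust prior, median centring, all 5 arrays at 21 hpf in the fit, the replicate number as a block, another threshold or fold, an estimated correlation, the mean over probe sets of a gene, other matching of random sets, control morpholino in place of untreated embryos as the age of 21 hpf, and leaving out each morpholino array in turn. Chosen after seeing the data were the as-deposited values, centring on bacterial spike-in controls, the untreated array as the reference for the Spt5 morpholino, and dim values raised to log2 5. The procedure was tested on simulated data for the comparison of morpholinos with 8457 probe sets, 200 of them changed, in 10 runs. limma recovered 33.3% of changes of 0.5, 97.9% of changes of 1 and 99.7% of changes of 2 on the log2 scale. Of its calls 7.2% were false, and camera found a shifted list in 10 of 10 runs. In the data 4001 of 8457 probe sets were called, far more than were changed in the simulation, so these rates do not carry over to the data. In the same simulation 0 of 40 random sets fell outside percentiles 2.5 to 97.5. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.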

Results

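Spt5 is a subunit of DSIF, a factor that binds RNA polymerase II and takes part in promoter-proximal pausing and in transcript elongation. Zebrafish embryos of the TL strain were injected at the start of cleavage with a morpholino, an antisense oligonucleotide, directed against it, and RNA of whole embryos was hybridised to Affymetrix zebrafish arrays. The 6 arrays comprised 2 of embryos injected with 2.5 pmol of the Spt5 morpholino, 2 of embryos injected with 2.5 pmol of a control morpholino, 1 of untreated embryos at the same age of 21 hours post-fertilization (hpf), and 1 of untreated embryos at 5 hpf. Median intensities were 26.8 and 36.1 on the Spt5 morpholino arrays, 32.4 and 43.8 on the control morpholino arrays, 40.1 on the untreated array at 21 hpf and 18.1 at 5 hpf. An intensity of at least 32 was reached by 7156 and 8152 of 15502 probe sets with the Spt5 morpholino, 7828 and 8961 with the control morpholino, 8618 in untreated embryos at 21 hpf and 6523 at 5 hpf. Across probe sets, the log2 intensities of the 2 Spt5 morpholino arrays correlated with r = 0.951 and those of the 2 control morpholino arrays with r = 0.953, against 0.916 to 0.919 between these groups. The array at 5 hpf correlated with the other 5 at 0.613 to 0.620. Probe sets are not independent replicates. The ratio of 3' to 5' signal, a sign of RNA integrity and labelling, was taken from actin and GAPDH control probe sets. For actin it was 6.94 and 6.99 with the Spt5 morpholino and 9.91 and 9.61 with the control morpholino. It was 7.59 in untreated embryos at 21 hpf and 1.96 at 5 hpf. For GAPDH, in the same order, it was 1.39, 1.42, 1.70, 1.76, 1.24 and 0.95. The actin is acta1, a muscle actin, so its ratio may also follow the level of muscle transcripts. This has little bearing between the morpholinos, where the acta1a transcript differed by -0.06 (log2, limma adjusted p = 0.594). The GAPDH ratio was also higher with the control than with the Spt5 morpholino.

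Spt5 morpholino embryos were compared with control morpholino embryos at 21 hpf to find the genes that respond to the Spt5 morpholino. The transcript of supt5h itself, which encodes Spt5, differed by 0.05 ± 0.14 (log2, SE, n = 2 and 2; limma adjusted p = 0.804), with means of 7.57 ± 0.21 (SD) and 7.52 ± 0.13. A morpholino that blocks translation leaves its mRNA in place, so this value does not check the knockdown. Transcripts of embryonic globins, several muscle contractile proteins, a neural crest marker and many cell cycle genes fell, while those of many p53 pathway genes and regulators of the blastula and gastrula rose. Of 8457 probe sets tested, 4001 (47.3%) passed the adjusted p of 0.05 in limma, 2059 higher and 1942 lower in the Spt5 morpholino embryos. The median size of a called difference was 0.69 on the log2 scale, and 979 called probe sets differed at least 2-fold, 397 higher and 582 lower. Every Spt5 morpholino array lay at least 2-fold from every control morpholino array for 653 probe sets, 230 above and 423 below. The 2 other splits of the 4 arrays gave 0 and 0. At the gene level, 1286 of 5691 named genes rose and 1397 fell.

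The split between higher and lower depends on how the arrays are scaled. Without normalization between arrays the median probe set was lower by a log2 difference of -0.21 in the Spt5 morpholino embryos, and after centring on bacterial spike-in controls by -0.27, against 0.04 after quantile normalization. All changes are given relative to the quantile-normalized distribution. The as-deposited values called 305 probe sets higher and 1350 lower, and spike-in centring 910 higher and 3516 lower. supt5h was then at -0.16 and -0.22, and at -0.19 against the untreated embryos. Leaving out 1 array at a time gave 2531 changed probe sets without Spt5 morpholino replicate 1 and 2352 without replicate 2, and 2724 and 2788 without control morpholino replicates 1 and 2. The filter, set at 2 arrays of a fit, then also removed probe sets bright only in the group left with 1 array. Without the filter on dim probe sets 874 passed.

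The 12 largest falls among named genes included markers of neural crest, blood and muscle. crestin, a marker of neural crest, fell at least 9.47-fold (adjusted p = 3.6e-04), and gch2, which makes pteridine pigment precursors in that lineage, fell at least 3.08-fold (adjusted p = 0.0037). The embryonic alpha globin hbae3 fell by 3.71 ± 0.11 on the log2 scale (adjusted p = 4.0e-04), and slc4a1a, the erythrocyte anion exchanger, at least 1.21-fold. Among muscle genes, creatine kinase ckmb fell by 3.37 ± 0.14 and the fast myosin light chain mylpfa by 2.97 ± 0.17. The cardiac light chains myl7 and cmlc1 fell at least 5.46-fold and 3.82-fold. The others were in itih2 (at least 6.35-fold), mydgf (4.65-fold), ddx42 (3.91-fold) and mocs3 (1.11-fold), each a lower limit because the Spt5 morpholino arrays lay below an intensity of 32. Among the largest measured falls of probe sets without a gene name, 1 was at least 6.71-fold, with Spt5 morpholino values below that intensity. Another, above it in both groups, was by 3.57 ± 0.10 on the log2 scale, and their order is not established.

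The 12 largest rises among named genes were of mixed function. gadd45aa and gadd45bb, members of a family induced by growth arrest and DNA damage, rose at least 9.31-fold (adjusted p = 4.5e-04) and by a log2 difference of 2.19 ± 0.12. The immediate early gene fosab rose by 2.80 ± 0.11, with all 4 of its probe sets called and the smallest difference at 2.15, and the nuclear receptor gene nr4a1 rose at least 1.40-fold. ctsba, which encodes the lysosomal protease cathepsin B, rose by 2.68 ± 0.10, the amino acid transporter subunit slc3a2b by 2.39 ± 0.11 and itm2ba by 2.39 ± 0.16. rcvrn3 (at least 2.69-fold), tcima (1.96-fold), cyp51 (1.84-fold), itga6b (1.34-fold) and sall4 (1.19-fold) rose from below an intensity of 32 on both control morpholino arrays. The other probe set of sall4 gave 0.04 and was not called, while the other tested probe sets of tcima and cyp51 were called in the same direction. Among the largest measured rises of probe sets without a gene name, 1 was at least 15.3-fold, from control morpholino values below an intensity of 32. Another, above it in both groups, was by 4.72 ± 0.10, and their order is not established. Without the filter on dim probe sets, gch2, slc4a1a, tcima, itga6b, sall4 and nr4a1 had adjusted p of 0.0599, 0.0791, 0.171, 0.153, 0.0732 and 0.0700. Against the untreated embryos, tcima, itga6b and itm2ba were not called, and all named genes apart from supt5h kept their side. The same 2 Spt5 morpholino arrays enter both comparisons, so part of this agreement is built in. The rises of slc3a2b, gadd45aa and gadd45bb were larger there, at 2.80, 4.51 and 2.83. Those of the remaining named genes were smaller than over the control morpholino, among them fosab at 1.57, ctsba at 1.22 and itm2ba at 0.56.

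**Figure D1:**
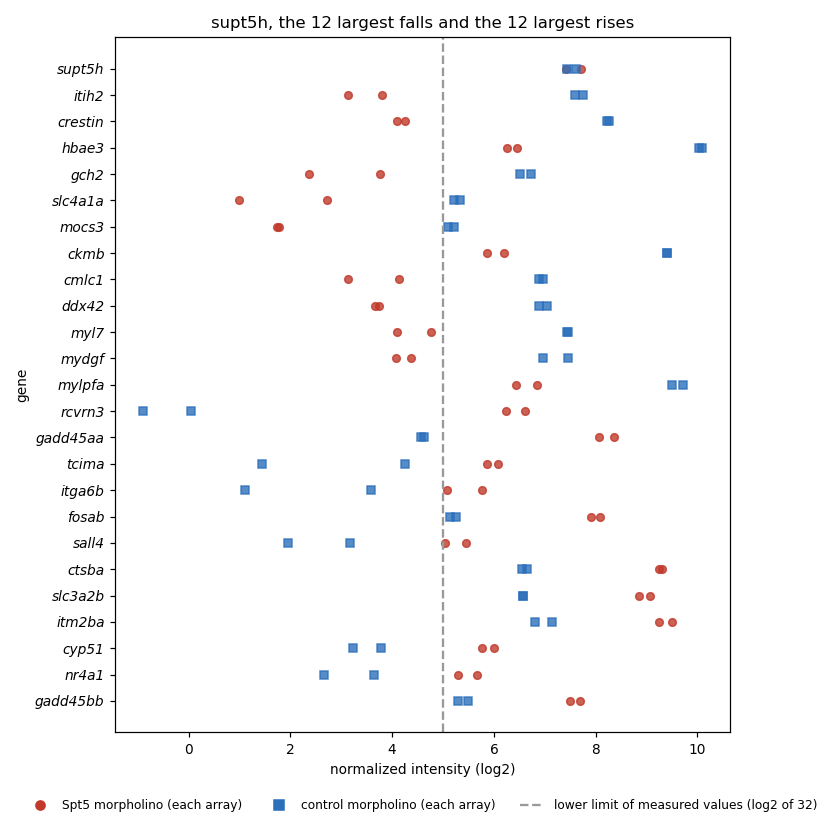
Normalized log2 intensity of supt5h, the 12 largest falls and the 12 largest rises on each of the 2 Spt5 morpholino arrays (circles) and the 2 control morpholino arrays (squares). The dashed line marks an intensity of 32. The groups are separate for every gene except supt5h, whose means were 7.57 and 7.52.

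Among the 26 lists fixed before the data were examined, the cell cycle and DNA replication list had the smallest p. Of its 41 tested genes, 36 fell and 0 rose, also when adjusted over the list alone, with a median log2 difference of -1.09 (camera adjusted p = 5.3e-12; adjusted p = 0.253 with an estimated correlation). The ribonucleotide reductase subunit rrm1 fell by 2.60 ± 0.11, the replicative helicase subunit mcm7 by 1.54 ± 0.09, the single-strand binding subunit rpa2 by 1.45 ± 0.10 and the mitotic kinase plk1 by 1.34 ± 0.09, and mcm4 was at -1.30 ± 0.10. The p53 pathway and apoptosis list moved the other way, with 17 of 19 genes risen and 1 fallen over all probe sets and adjusted over the list alone (median 0.92; adjusted p = 1.2e-06; adjusted p = 0.253 with an estimated correlation). The pore-forming baxa rose by 1.64 ± 0.09, the BH3-only gene pmaip1 at least 2.22-fold, and the member that fell was ckap2l, a spindle protein gene, by 1.99 ± 0.11. All list comparisons between the morpholinos share a difference in the actin 3' to 5' ratio, which was 6.94 and 6.99 with the Spt5 morpholino and 9.91 and 9.61 with the control morpholino. The GAPDH ratio was 1.39 and 1.42 with the former and 1.70 and 1.76 with the latter. Blastula and gastrula regulators rose in 24 of 31 cases with 0 fallen, the same when adjusted over the list alone (median 0.73; adjusted p = 5.9e-08; adjusted p = 0.253 with an estimated correlation). The ventralizing homeobox genes vox and ved rose by 1.49 ± 0.09 and 2.19 ± 0.18, irx7 by 1.15 ± 0.09, cebpb by 1.27 ± 0.10 and szl at least 1.99-fold. Adjusted over the named genes alone, the number risen was 13 for blastula regulators and 11 for the p53 list without Spt5 morpholino replicate 2, and 10 and 8 on the as-deposited values. Over the 26 lists, 73 of 208 such counts with 1 array left out moved by more than 1.5-fold, to which members removed by the filter contribute.

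Most called members of the muscle and blood lists fell, and those that rose were of mixed kinds. In the skeletal muscle list 18 of 30 genes fell and 7 rose (19 and 7 adjusted over the list alone; median -0.80; adjusted p = 0.0118; adjusted p = 0.419 with an estimated correlation). The second probe set of mylpfa fell by 2.95 ± 0.09, ckma by 2.59 ± 0.09 and the light chain myl1 by 2.05 ± 0.09, whereas the risen members were the transcription factor genes myod1, myf5, mef2ca and mef2d and the structural genes tnnt3b (at least 1.65-fold), neb and ttn.2. Against the untreated embryos mef2ca was lower in the Spt5 morpholino embryos, at -0.78 (adjusted p = 0.0191), and lower still with the control morpholino (-1.73), so its rise is one over the control morpholino level alone. The erythroid list had 12 of 21 genes fallen and 3 risen, also when adjusted over the list alone (median -0.88; adjusted p = 0.0244; adjusted p = 0.419 with an estimated correlation). The globins hbbe3, hbbe2 and hbae3 fell by 2.56 ± 0.09, 2.58 ± 0.15 and 3.45 ± 0.15, and urod, of heme synthesis, by 1.85 ± 0.09. The risen members were lmo2, the transcription factor gene klf3 and the nucleotidase gene nt5c2l1, and the transcription factor gene znfl2a fell by 0.88 ± 0.15. With values under an intensity of 32 set to it, the medians were -0.63 for muscle and -0.76 for erythroid genes. The muscle call was lost without control morpholino replicate 2 (adjusted p = 0.0682) and with spike-in centring (0.0712), and the erythroid call without control morpholino replicates 1 and 2 (0.0578 and 0.0704) and with spike-in centring (0.0673). The heart list had 5 of 14 genes fallen and 6 risen, also when adjusted over the list alone, with a median of 0.03 but a mean of -0.55 and no call (adjusted p = 0.995). nexn fell by 2.07 ± 0.12 and the ventricular myosin gene myh7 at least 2.80-fold, while the transcription factor gene hand2 rose by 0.76 ± 0.09. On the as-deposited values the list was lower (adjusted p = 0.0048; adjusted p = 0.998 with an estimated correlation). Without control morpholino replicate 1 or 2 the heart list turned higher without a call. The filter then removed genes bright only on the control morpholino arrays, such as cmlc1, so this turn is partly one of the genes tested. Adjusted over the named genes alone, 12 muscle genes fell without control morpholino replicate 2, against 19 with all arrays, and 4 and 1 rose without Spt5 morpholino replicates 1 and 2, against 7.

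Myeloid, immediate early and respiratory chain genes also moved as lists, with calls that rest on single arrays or settings. Of 20 myeloid list genes on the array 7 were tested, and mpx, lyz and spi1b were not among them. The matrix protease gene mmp9 and the oxidase subunit gene cyba passed the filter only through the Spt5 morpholino arrays. Of the 7 tested, 5 rose and 0 fell (6 and 0 adjusted over the list alone; median 0.69, or 0.45 with dim values set to an intensity of 32; adjusted p = 0.0076; adjusted p = 0.419 with an estimated correlation). Among the risen were cebpb, mmp9 at least 2.08-fold, cebpa by 0.69 ± 0.09 and cyba at least 1.08-fold. That call was lost without Spt5 morpholino replicate 2 (adjusted p = 0.0597) and without the filter on dim probe sets (0.363). Without Spt5 morpholino replicates 1 and 2, 3 and 2 myeloid genes rose. Of 20 immediate early genes 10 rose and 3 fell, also when adjusted over the list alone (median 0.42; adjusted p = 0.0365; adjusted p = 0.494 with an estimated correlation). With the replicate number as a block the camera adjusted p of this list was 0.0890. Besides fosab, ier2a rose by 1.52 ± 0.13, btg2 by 0.89 ± 0.09 and atf3 at least 2.01-fold. The immediate early call was also lost without Spt5 morpholino replicate 1, replicate 2 or control morpholino replicate 2, and against the untreated embryos. In the oxidative phosphorylation list 20 of 74 genes fell and 2 rose (13 and 1 adjusted over the list alone; median -0.14; adjusted p = 0.0244; adjusted p = 0.666 with an estimated correlation). cox6b1 fell by 1.35 ± 0.10, ndufs1 by 0.83 ± 0.09 and ndufa4b at least 1.58-fold, and atp5mea was at -1.20 ± 0.14. The call was lost without Spt5 morpholino replicate 2 (0.167) and on the as-deposited values (0.260). Adjusted over the named genes alone, 21 of its genes fell, against 11 to 14 with 1 array left out. With an estimated correlation 0 of the 26 lists was called, and 3 had an unadjusted p under 0.05.

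No call was made for 18 lists, heart among them; in the others members moved both ways or few moved. In the list of Spt5 and the elongation machinery 5 of 26 genes rose and 3 fell (2 and 3 adjusted over the list alone; adjusted p = 0.519). ell2 and ell, subunits of elongation complexes, rose by 1.39 ± 0.09 and 0.88 ± 0.11, while the Paf1 complex gene leo1 fell by 1.87 ± 0.23 and the histone chaperone gene ssrp1a was at -1.30 ± 0.10. Of 68 ribosomal protein genes 3 fell and 1 rose (1 and 1 adjusted over the list alone; adjusted p = 0.783). The paralog rpl22l1 fell by 1.24 ± 0.09 and rps27l rose by 0.99 ± 0.09. In the heat shock list 4 of 21 rose and 4 fell (adjusted p = 0.828), with the small heat shock gene hspb1 up by 1.36 ± 0.09 and hspb8 down by a log2 difference of -1.22 ± 0.09. The unfolded protein response list had 5 risen and 4 fallen of 19 (adjusted p = 0.591), with canx up by 0.76 ± 0.10, and the interferon list 2 risen and 0 fallen of 4 (adjusted p = 0.136), with isg15 up by 1.42 ± 0.10. For these 3 lists the counts adjusted over the list alone were the same.

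Patterning and nervous system lists were mixed. In the somite segmentation and Notch list 10 of 23 genes rose and 5 fell, also when adjusted over the list alone (adjusted p = 0.142), with the posterior regulators cdx4 and tbx16 up by 1.06 ± 0.09 and 1.14 ± 0.10 and the Notch ligand gene dld down at -0.80 ± 0.09. That list was called higher without the filter on dim probe sets (0.0343) and against the untreated embryos (0.0315), with adjusted p = 0.342 and 0.408 with an estimated correlation. The interferon list was called higher without the filter (0.0144; adjusted p = 0.342 with an estimated correlation). Of 29 Hox genes 4 rose and 4 fell (4 and 3 adjusted over the list alone; adjusted p = 0.591), with hoxc13a down at least 1.82-fold. The neuronal list had 12 of 27 genes fallen and 4 risen (12 and 5 adjusted over the list alone; adjusted p = 0.193), mllt11 at -1.62 ± 0.12 among the former and gata3 at 1.18 ± 0.09 among the latter. Neural progenitor genes gave 5 risen and 6 fallen of 29 (5 and 5 adjusted over the list alone; median 0.11, mean below 0; adjusted p = 0.727), with the radial glia genes fabp7a down at least 2.32-fold and gfap at -1.20 ± 0.09. In the eye list 3 rose and 4 fell of 8, also when adjusted over the list alone (adjusted p = 0.801), with mab21l1 down at least 3.49-fold. Maternal and germ cell genes gave 3 risen and 1 fallen of 8, also when adjusted over the list alone (adjusted p = 0.304), the latter being ybx1 at -0.91 ± 0.14.

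The remaining lists covered surface, axial and internal tissues. The epidermis list had 14 of 34 genes risen and 7 fallen (18 and 7 adjusted over the list alone; adjusted p = 0.201), with grhl1 up by 1.81 ± 0.19 and the calcium-binding genes s100a10b and icn both at -1.35. Adjusted over the named genes alone 16 rose, against 6 to 10 with 1 array left out, 5 without the filter on dim probe sets, 5 with spike-in centring and 1 on the as-deposited values. In the notochord and hatching gland list 7 of 20 rose and 5 fell (adjusted p = 0.482; median 0.16, mean -0.08), with lamb1a at 1.09 ± 0.09, agr2 at -1.34 ± 0.09 and col9a2 at -1.28 ± 0.11. The yolk, liver and gut list had 7 risen and 12 fallen of 28 (8 and 12 adjusted over the list alone; adjusted p = 0.414). Fibrinogen genes fga and fgg fell at least 2.01-fold and by 1.62 ± 0.09, the retinol carrier gene rbp4 fell by 1.98 ± 0.13, and the regulator hnf4a rose at least 2.02-fold. Pronephros genes gave 4 risen and 4 fallen of 9 (adjusted p = 0.828; median 0.06, mean -0.41), with cdh17 down at least 3.96-fold and atp1a1a.4 at -2.07 ± 0.10. Pigment and neural crest genes gave 5 risen and 3 fallen of 18 (adjusted p = 0.828; median 0.06, mean -0.36), the fallen being crestin, gch2 and dct. Vascular genes gave 2 risen and 2 fallen of 11 (adjusted p = 0.995; median -0.03, mean above 0), gata2a at 1.37 ± 0.14 and flt4 at -1.10 ± 0.10 among them. For the notochord, pronephros, pigment and vascular lists the counts adjusted over the list alone were the same.

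**Figure D2:**
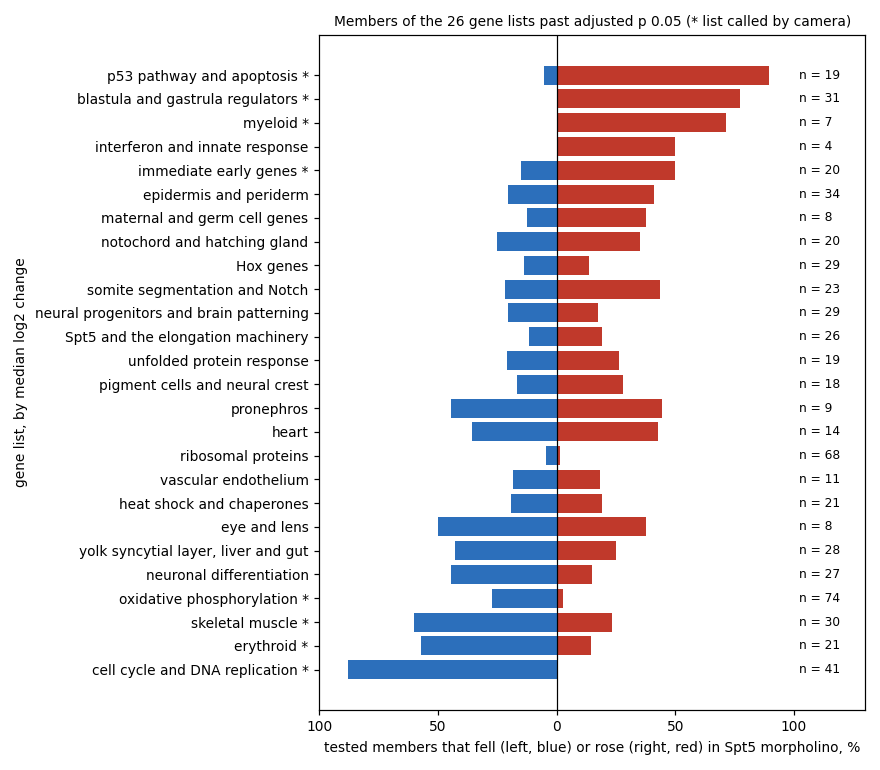
Percentage of the tested members of each of the 26 gene lists that fell (left, blue) or rose (right, red) in Spt5 morpholino against control morpholino embryos at a limma adjusted p of 0.05, ordered by the median log2 difference of the list. The cell cycle list (36 of 41 fallen) and the p53 list (17 of 19 risen) lie at the ends.

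Untreated embryos at 21 hpf were compared with untreated embryos at 5 hpf to place these genes in development. There was 1 array per age, so the differences have no replicate check and no test. Of 9294 probe sets compared, 2806 were at least 2-fold higher and 3053 at least 2-fold lower at 21 hpf, about a median difference of -0.16. The 3' to 5' ratio was 1.96 at 5 hpf and 7.59 at 21 hpf for actin, and 0.95 and 1.24 for GAPDH. The actin is a muscle actin and muscle genes were higher at 21 hpf, so its ratio is not a measure of RNA integrity alone. Any difference in RNA integrity is shared by all values for the ages. The as-deposited values gave 4292 higher and 1705 lower about a median of 0.70, and spike-in centring 4230 and 1740 about 0.68. The 10 largest differences on the higher side were in genes of mixed kinds. Each value is a lower limit because the 5 hpf value lay below an intensity of 32. afp4 was higher by at least 121-fold, fabp1b.1 by 50.3-fold, gamt by 47.7-fold, and apoa4b.1 by 42.2-fold. The globin hbbe3 was higher by at least 39.9-fold, the keratin krt17 by 36.66-fold, the parvalbumin pvalb9 by 31.2-fold, apoc2 by 27.0-fold, mdka by 24.3-fold and tuba8l3 by 14.5-fold. The lower side, given in the same way, included maternal and oocyte genes. The linker histone gene h1m was lower by at least 123-fold, nanog by 120.3-fold, spink2.1 by 83.9-fold, and cth1 by 81.7-fold. The oocyte kinase gene wee2 was lower by at least 44.9-fold, the germ plasm organizer buc by 34.5-fold, ppp1r3c2b by 25.1-fold, gtf3ab by 24.3-fold, btg4 by 23.0-fold and mcm6l by 16.2-fold.

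By list, yolk, liver and gut genes had a median difference of 5.73 between 21 and 5 hpf, skeletal muscle genes 4.29, heart genes 4.2, epidermal genes 4.1, Hox genes 3.43, erythroid genes 2.29, ribosomal protein genes 2.1 and oxidative phosphorylation genes 1.72, each above the middle 95% of 10000 random lists of like expression. Maternal and germ cell genes had a median of -4.64, below all random lists, and blastula and gastrula regulators one of -1.33, at percentile 0.37. With dim values set in the same way these medians were -3.02 and -0.52. Genes of the elongation machinery had a median of -1.01, at percentile 0.66, and supt5h itself was 0.67 higher at 21 hpf. The cell cycle list (0.12, percentile 88.5) and the p53 list (-0.69, percentile 20.7) lay within the range of random lists. On the as-deposited values the p53 list had a median of 0.37, where that of all probe sets was 0.70, and with the mean over the probe sets of a gene the cell cycle list had a median of -0.62. The Hox list lay inside the random range on the as-deposited values (percentile 71.3), with median centring (68.0) and with spike-in centring (69.7). The elongation machinery had a median of -0.45 (percentile 3.15) on the as-deposited values and -0.48 (2.7) with spike-in centring, both inside the middle 95%, and blastula and gastrula regulators one of -0.25 (2.5) on the as-deposited values, at its edge.

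The series uses the difference between ages to give the activation of genes affected by the Spt5 morpholino. The 1942 probe sets that fell in Spt5 morpholino embryos had a median 21 minus 5 hpf difference of 0.61, above all of 10000 random sets matched on intensity, whose middle 95% ran from 0.16 to 0.35. Of these, 43.1% were at least 2-fold higher at 21 hpf, against 35.6% of matched probe sets. The 2059 that rose had a median of 0.06, below all random sets (0.19 to 0.36), with 24.6% at least 2-fold lower at 21 hpf against 21.0% of matched probe sets. Probe sets that gained more than 4 log2 units between ages fell in 36.8% and rose in 22.3% of 692 cases. Those that lost more than 4 rose in 44.0% and fell in 12% of 50. These bins hold only probe sets that passed the filter on the morpholino arrays. One dim on both control morpholino arrays passed only through the Spt5 morpholino arrays. This favours rises among genes that are dim at 21 hpf, so the shares in the second bin are not free of the filter. Across all tested probe sets the relation was weak, with Pearson's r = -0.15 and Spearman's rho = -0.10. Probe sets are not independent replicates. The position of the risen set depended on 1 array and on the setting: it was at percentile 15.3 without Spt5 morpholino replicate 1, 58.05 on the as-deposited values, 11.5 with spike-in centring, 14.4 without the filter, 15.4 with dim values set to an intensity of 32 and 5.57 for the 230 probe sets at least 2-fold apart in every pair of arrays. The matched mean, also behind the shares above, includes the Spt5 morpholino arrays. Fallen sets thus have a higher control morpholino level than their matches, and risen sets a lower one. Matched on the control morpholino level alone, the risen set was at percentile 3.05, inside the middle 95%. The fallen set stayed above all random sets in each of these.

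**Figure D3:**
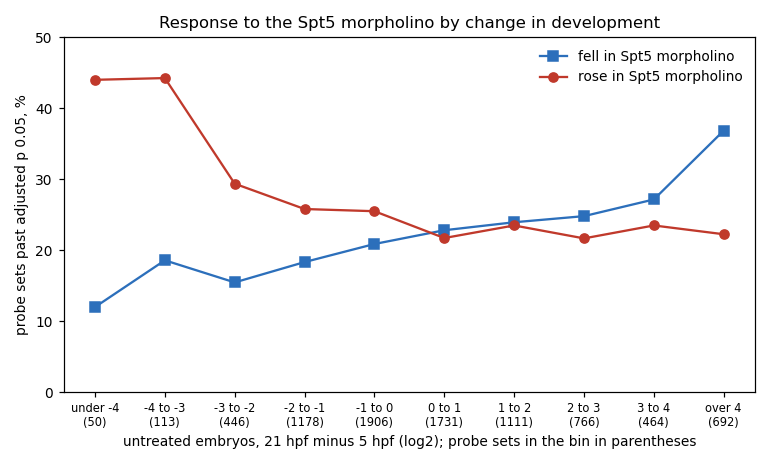
Percentage of probe sets that fell (squares) or rose (circles) in Spt5 morpholino embryos at a limma adjusted p of 0.05, by bins of the log2 difference between untreated embryos at 21 and 5 hpf, with the number of probe sets in each bin in parentheses. In the bin over 4, 36.8% fell, and in the bin under -4, 44.0% rose. Only probe sets that passed the filter on the morpholino arrays are included.

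Control morpholino embryos were compared with untreated embryos at 21 hpf as the background of injection or of another batch of embryos. The lone untreated array was assumed to vary like the morpholino groups. The largest measured rises with the control morpholino were in casp8 and phlda3 of the p53 list, by at least 2.31-fold and 4.43-fold. The others were in isg15 (at least 2.11-fold), ndufa4b (1.62-fold) and rspo1 (1.14-fold), all at limma adjusted p of 0.0058 to 0.0178. Each is a lower limit because the untreated value lay below the intensity set for the filter, so their order is not established. The p53 list members rps27l and sesn3, above that intensity on every array at 21 hpf, were higher by 2.01 and 1.94 (log2). Both differences exceed the limits given for casp8, isg15, ndufa4b and rspo1. itm2ba, fabp7a and the lipid carrier gene apom were lower, at -1.83 ± 0.20, -1.82 ± 0.14 and -1.77 ± 0.11, and mef2ca and fosab by at least 2.29-fold and 2.32-fold (adjusted p of 0.0156 to 0.0320). The probe set of fosab named here differs from the one that led the rises in the Spt5 morpholino embryos. Of 8701 probe sets, 250 passed the adjusted p of 0.05 in limma, 152 higher and 98 lower, and 145 of them differed at least 2-fold. The count was 2 without Spt5 morpholino replicate 1, 2 without replicate 2, 10 and 7 without control morpholino replicates 1 and 2, 58 on the as-deposited values and 0 without the filter on dim probe sets, where 2013 had an unadjusted p under 0.05. The actin 3' to 5' ratio was 9.91 and 9.61 on the control morpholino arrays and 7.59 on the untreated array, and the GAPDH ratio 1.70 and 1.76 against 1.24.

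The p53 pathway list was higher in the control morpholino embryos than on the lone untreated array, whose spread is taken from the morpholino groups, with a median of 0.87 and 10 of 19 genes called (camera adjusted p = 9.0e-12; adjusted p = 0.401 with an estimated correlation). The number called was 6 and 7 without Spt5 morpholino replicates 1 and 2, 7 and 8 without control morpholino replicates 1 and 2, 6 on the as-deposited values and 0 in limma without the filter, where 12 of 23 were higher at an unadjusted p under 0.05. Against the untreated embryos the Spt5 morpholino embryos had a median of 2.32, with 18 of 19 genes called higher (adjusted p = 0.229 with an estimated correlation). Camera placed yolk, liver and gut genes lower with the control morpholino (4 of 28 called; median -0.16; adjusted p = 0.0027), and also cell cycle genes (median -0.14; adjusted p = 0.0027) and neural progenitor genes (median -0.19; adjusted p = 0.0450), each with an adjusted p = 0.401 with an estimated correlation. Few members of the latter lists were called, 1 of 41 and 2 of 29. Of the 2059 probe sets that rose and the 1942 that fell between the morpholinos, 1968 and 1863 lay on the same side of the untreated embryos. The same 2 Spt5 morpholino arrays enter both comparisons, so part of this agreement is built in and it is not independent support. The untreated level was nearer to the Spt5 than to the control morpholino level for 326 of the risen probe sets (15.8%) and 261 of the fallen (13.4%).

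**Figure D4:**
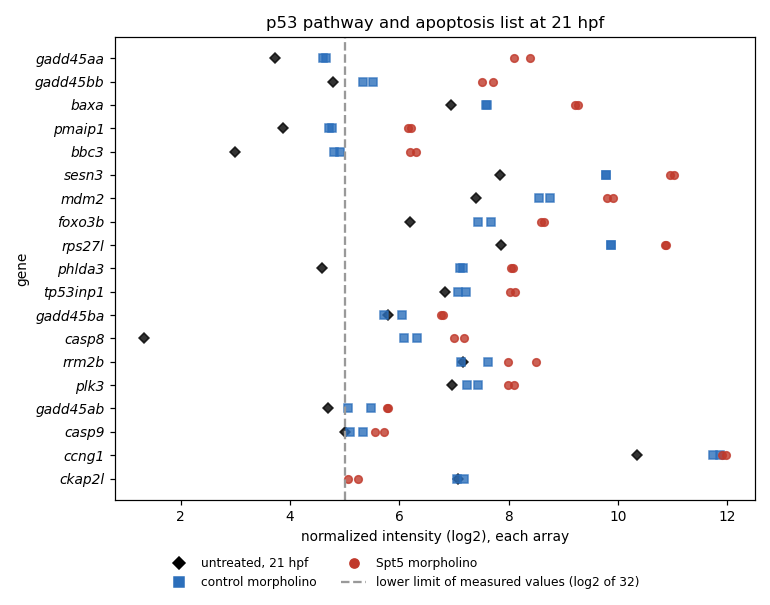
Normalized log2 intensity at 21 hpf of the 19 tested genes of the p53 pathway and apoptosis list on the untreated array (diamonds), the 2 control morpholino arrays (squares) and the 2 Spt5 morpholino arrays (circles), ordered by the Spt5 minus control difference. The dashed line marks an intensity of 32. casp8 was at 1.34 on the untreated array and averaged 6.21 and 7.10 in the control and Spt5 morpholino embryos. pmaip1, gadd45aa and bbc3 lay below the dashed line on the untreated and control morpholino arrays.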

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

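Of the alternatives, the as-deposited values, spike-in centring, the untreated array as reference, and dim values raised to log2 5 were chosen after seeing the data. Array signal over background, and 2 arrays per group, limit every count. The fall of the cell cycle list and the rise of the p53 and blastula lists kept their direction and call under every setting except the estimated correlation. Their estimated correlations were -2.0e-04, -0.031 and -0.020, all below the preset 0.01. Their calls were thus lost there through the 2 residual degrees of freedom that this setting uses, and not through correlation between genes. Of 233 values of the 25 named genes under alternatives other than leaving out an array, 221 kept direction and call, as did 64 of 66 with 1 array left out. In 34 more cases, the gene could not be tested because the filter removed it, and the 2 that turned were of supt5h. All named genes but supt5h were chosen for the largest called differences on these same arrays. Their agreement across settings is therefore largely built in. Over all results, 352 of the values behind a comparison and 788 others were classed as the same. For a count this means within 1.5-fold of its main value, and for a test the same direction and side of 0.05. These classes do not measure how close the values were. Of the others, 28 and 17 lost a call or a place outside the random range, and 4 and 4 gained one. A further 40 and 158 were counts that moved beyond that limit, and 25 and 8 values turned. The cause was not tested except where stated.

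Without the filter, 15502 probe sets were tested: 874 changed, 342 higher and 532 lower, while 1133 were at least 2-fold apart in every pair (443 higher, 690 lower). The interferon list (adjusted p = 0.0144) and the somite list (0.0343) gained a call, and the myeloid list (0.363) lost it. The risen set had a 21 minus 5 hpf median of -0.073, 4298 probe sets were higher and 4934 lower at 21 hpf, and the p53 list's age difference was -0.070. In all, 0 probe sets differed between control morpholino and untreated embryos (2013 at an unadjusted p under 0.05).

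On the as-deposited values 1655 changed, 305 of them higher, and 68 were at least 2-fold higher in every pair. supt5h was at -0.16. The heart list gained a call (0.0048) and oxidative phosphorylation lost it (0.260). Lists without a call turned direction: heat shock, vascular and notochord genes (0.936 each) and pigment genes (0.161). The risen set's age median was 0.90, 4292 probe sets were higher and 1705 lower at 21 hpf, the p53 list's age difference was 0.37, and 58 probe sets differed between control morpholino and untreated embryos. With spike-in centring 910 were higher and 3516 lower, 103 higher and 771 lower in every pair, and supt5h was at -0.22. Skeletal muscle (0.0712) and erythroid genes (0.0673) lost their call. Heart (0.779), vascular (0.908), neural progenitor (0.932) and pronephros genes (0.839) turned without one. The risen set's age median was 0.80, and 4230 probe sets were higher and 1740 lower at 21 hpf. In these 2 settings the median probe set was lower in the Spt5 morpholino embryos, which moves rises to falls.

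With the untreated array as reference supt5h was at -0.19, immediate early genes lost their call (0.197), somite genes gained one (0.0315), and heat shock (0.334), pigment (0.554), neural progenitor (0.404) and pronephros genes (0.846) turned without one. An added 2-fold threshold left 979 changed (397 higher, 582 lower), by construction. A 1.5-fold limit in every pair gave 1761 (799 higher, 962 lower), against 5 and 0 in the other splits. With an estimated correlation 0 lists were called: the cell cycle, p53 and blastula lists had an adjusted p of 0.253, muscle, erythroid and myeloid genes 0.419, immediate early genes 0.494 and oxidative phosphorylation 0.666. The risen set's age median of 0.061 lay at percentile 3.05 when random sets were matched on the control morpholino level, the every-pair set's of -0.0079 at 5.57, and that with dim values raised to log2 5, 0.00, at 15.4. With the mean over the probe sets of a gene the cell cycle list's age difference was -0.62.

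Same-numbered replicates are not known to be paired, and their deviations from the group means correlated at 0.25 over the 2 numbers. With the replicate number as a block, 4439 probe sets changed, immediate early genes had an adjusted p of 0.0890, vascular genes turned direction (0.991), and no other list changed its call.

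Leaving out each array in turn leaves 1 residual degree of freedom, and the lone array is assumed to vary like the other group. A probe set still needed log2 5 on 2 arrays, so one bright only in the group of the lone array was not tested. Counts, calls and directions with an array left out therefore reflect the filter as well as the array. The number changed then ran from 2352 to 2788, higher from 975 to 1612 and lower from 1158 to 1463, the number of lists called from 5 to 7. supt5h ran from -0.10 to 0.20, the control against untreated count from 2 to 10 and the risen set's age median from 0.010 to 0.23. Adjusted p ran from 1.8e-04 to 0.0682 for muscle, 0.0164 to 0.0704 for erythroid, 0.0152 to 0.0597 for myeloid, 0.0357 to 0.251 for immediate early and 0.0088 to 0.167 for oxidative phosphorylation genes. Without a call, it ran from 0.271 to 0.818 for eye, 0.141 to 0.736 for heart, 0.563 to 0.981 for heat shock, 0.477 to 0.981 for pronephros, 0.418 to 0.981 for ribosomal protein and 0.744 to 0.947 for vascular genes.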

Other observations

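The gene lists described first, and the tests of the muscle and erythroid age difference, of array scaling for cell cycle genes, of another effect of the morpholino, of RNA quality and of transcription factors, were chosen after the result was seen. Those of the muscle and erythroid age difference and of array scaling for cell cycle genes replaced earlier ones whose outcome was fixed by the lists or by the direction of the scalings. Genes of DNA repair fell in Spt5 morpholino embryos, 12 of 18 with 0 risen (13 and 0 adjusted over the list alone; camera adjusted p = 2.6e-04; adjusted p = 0.301 with an estimated correlation). The checkpoint kinase gene chek1 was at -1.66 ± 0.10 and the polymerase subunit gene pold2 at -1.91 ± 0.14. Most of the fallen members are genes of DNA replication (pold1, pold2, pold3, pole2, rfc1, rfc3, rpa3 and lig1), so this overlaps in kind with the cell cycle and DNA replication list. Of the repair and damage genes, unga fell by 1.39 ± 0.10, xrcc5 by 0.78 ± 0.11 and msh6 at least 1.66-fold, while xrcc1, xrcc6, apex1, ddb1, ddb2 and chek2 were not called over all probe sets. Tubulins fell in 13 of 15 cases with 0 risen (13 fallen and 1 risen adjusted over the list alone; adjusted p = 2.6e-04; adjusted p = 0.301 with an estimated correlation), with tuba1b at -2.31 ± 0.10. Splicing factor genes fell in 23 of 70 cases and rose in 4 (21 and 4 adjusted over the list alone; adjusted p = 0.0168; adjusted p = 0.301 with an estimated correlation), with hnrnpabb at -2.19 ± 0.10.

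The other added lists had no call. Of 20 lysosome and autophagy genes 8 rose and 5 fell (10 and 5 adjusted over the list alone; adjusted p = 0.0668), with the autophagy receptor gene sqstm1 at 1.81 ± 0.10 beside ctsba at 2.68 ± 0.10. Of 57 translation factor genes 9 rose and 14 fell (9 and 13 adjusted over the list alone; adjusted p = 0.175), etf1b at 1.86 ± 0.11 and eif3ja at -1.74 ± 0.11 among them. Aminoacyl-tRNA synthetase and amino acid supply genes gave 3 risen and 9 fallen of 25 (adjusted p = 0.175). Cholesterol synthesis genes gave 3 and 1 of 7 (adjusted p = 0.227) with insig1 at 1.34 ± 0.09, and proteasome genes 1 and 7 of 41 (0 and 5 adjusted over the list alone; adjusted p = 0.252).

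The fall of cell cycle genes was set against array scaling and against a profile shifted towards that of younger embryos. The 41 tested genes had a median of -1.09 (bootstrap 95% interval -1.16 to -0.98), below the middle 95% of 10000 random lists of like intensity on the same arrays (-0.17 to 0.19), which argues against scaling, since it moves genes of like intensity alike. The 36 fallen genes had a median 21 minus 5 hpf difference of 0.40 (bootstrap 95% interval -0.83 to 0.86), and 16 of them were lower at 21 hpf. The median has the sign that a shift towards 5 hpf needs, but with an interval across 0 and members on both sides, such a shift and another effect of the morpholino cannot be told apart. A direct response to Spt5 loss remains an untested biological explanation.

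The rise of p53 pathway genes was set against injection, a shift towards 5 hpf and an effect of this morpholino apart from Spt5. All 17 risen genes were higher in control morpholino than in untreated embryos, 7 of them at least 2-fold, with a median of 0.87 (bootstrap 95% interval 0.37 to 1.86) against 0.99 between the morpholinos. Injection may therefore account for part of the level in both morpholino groups, although the untreated group is 1 array, which may differ in other ways, and injection alone does not explain the further rise over the control morpholino. The median age difference of the 17 risen genes was -0.69 (-2.11 to 1.32), with members on both sides of 0, which leaves a shift towards 5 hpf open. The series has 1 Spt5 morpholino and no mutant, so loss of Spt5 and another effect of this morpholino cannot be told apart.

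Some genes that rose between the morpholinos had an untreated level nearer to that of the Spt5 than of the control morpholino embryos. This held for 326 of 2059 risen probe sets, and for 292 of 1918 (15.2%) with median centring, 71 of 336 as deposited and 235 of 948 with spike-in centring, and because each scaling calls its own risen set and the number fell, scaling and another cause cannot be told apart. The covariance of the Spt5 minus control and untreated minus control differences was -0.0115, outside the 0.0084 to 0.0105 of 100 simulations with shared control arrays and no effect (r = -0.04 against 0.37 to 0.44). Real effects of opposite direction lower it, so the share due to the shared arrays stays open. The lowest actin 3' to 5' ratio of the control morpholino arrays was 1.27 times the highest of the other arrays at 21 hpf. Their GAPDH ratios, 1.70 and 1.76, were also the highest. RNA quality or labelling of the control morpholino arrays is therefore a candidate explanation for these genes.

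A hypothesis for the muscle and blood genes is that the Spt5 morpholino profile is partly that of a younger embryo. Both lists as a whole are higher at 21 than at 5 hpf, so the fallen members were set against the other tested members of their list. The median 21 minus 5 hpf difference was 4.72 for 18 fallen and 2.7 for 12 other muscle genes, a gap of 2.03 (permutation within the list, p = 0.0288). For 12 fallen and 9 other erythroid genes it was 2.78 and 1.94, a gap of 0.84 (permutation within the list, p = 0.496). Genes are not independent replicates, and fallen and other members were not matched on intensity. A fallen member had to be bright enough with the control morpholino at 21 hpf to pass the filter, which by itself favours a larger age difference. The gap for muscle genes has the sign that a younger profile needs, but the test does not separate it from this. For erythroid genes the test leaves a younger profile open. With 1 array per age, neither list separates a younger profile from a failure to express late genes.

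A second hypothesis is that transcription factors of a tissue were higher, and its other genes lower, in Spt5 morpholino embryos. Within the 13 cell type lists that hold both kinds, the median of transcription factors exceeded that of other members by 1.04 log2 on average, and the difference was above 0 in 13 of 13 lists (permutation within lists, p = 0.0001, the smallest that 10000 permutations can give). Genes are not independent replicates, so this p does not measure the spread between embryos. The difference was 0.014 for pigment genes, and the pronephros and epidermis lists held 1 and 2 factors. Of 78 transcription factors 34 rose and 11 fell (median 0.28), and of 164 other members 33 rose and 78 fell (median -0.31). The assignment of genes was corrected once after the result was seen, from an incomplete first version that gave 1.07, and with dim values raised to log2 5 the difference was 0.76. With the untreated array as reference, and the same Spt5 morpholino arrays, it was 1.01, although the factor gene mef2ca was then lower. Between untreated embryos at 21 and 5 hpf the same split gave -1.94 (permutation within lists, p = 0.0001, again the smallest that 10000 permutations can give). So a profile shifted towards 5 hpf would also produce it, and the test does not separate a role of Spt5 from a delay.

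A further hypothesis, that an elongation factor matters more for long genes, predicted lower expression of genes with a longer genomic span. Over 5676 of 5691 genes (99.7%) with a span in the RefSeq annotation, Spearman's rho between span and log2 difference was 0.039, which is on the other side of 0 from the prediction. Genes are not independent replicates. In the longest 20% by span, with a median of 65.3 kb, 21.1% of genes fell and 25.7% rose, and in the shortest, with a median of 3.94 kb, 24.6% fell and 21.7% rose.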
